A study of Onthophagus taurus with 60 samples.

How the data were processed

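RNA was measured in 8 epidermal regions of male prepupae of Onthophagus taurus, a dung beetle whose males carry horns. A prepupa is the end of the larval stage, when the epidermis has separated from the larval cuticle and forms the shape of the pupa. The regions were the wing of the mesothorax (T2 wing), 5 regions of the prothorax (thoracic horn, anterior margin, posterior margin, carinated margin and the dorsal centre, called dorsal prothorax here), the support structures of the abdomen, which are paired projections of the body wall, and the dorsal head. Each tissue had 6 biological replicates, per the labels, and the wing and the carinated margin were each sequenced as separate left and right libraries of the same 6 individuals. Dorsal prothorax and dorsal head were taken as contrast tissues without a known tie to wings, per the series description.

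RNA was extracted with the Qiagen RNeasy Plus Micro kit and libraries were made with the Illumina TruSeq Stranded mRNA kit, per the labels' protocols. Trimmomatic 0.32, Bowtie2 2.3.2, RSEM 1.3.0 and DESeq2 are named per the submitters' processing notes, which give no role for each. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited a single table of expected counts, estimates that need not be whole, for 23725 RefSeq transcripts in 60 columns. Of its values 29.71% lay further than 0.001 from a whole number, and column totals differed, so the counts had not been scaled to a common total. Expected counts divide reads between transcripts of a gene and between near-identical genes, so that the level of a single transcript is less certain than that of its gene. All 60 columns could be mapped to a tissue by name.

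Gene names came from a RefSeq gene table of assembly IU_Otau_3.0, used for names and for the order of genes only. Accessions were matched without their version suffix. Of the 23725 transcripts 15104 matched a gene, 10670 genes in all, and these carried 72.15% of all counts. Nearly all symbols were locus numbers. Symbols of another kind belonged to 34 genes and appeared to be shortened, so no function is assigned to them here. All 18 gene lists fixed in advance (wing network, limb axis, head patterning, Hox, sex and horn, hormone response, signalling, cuticle and chitin, pigment and tanning, cell cycle, cell death, muscle, neuron, haemocyte, fat body, trachea, stress, and ribosome and mitochondria) matched 0 genes, which made the list tests void, including those for markers of other cell types.

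Columns of the wing and the carinated margin are numbered 1 to 12 with no side. Their deviations from the tissue mean showed which columns shared an individual. Column k correlated with column k+6 at r = 0.132 to 0.281 in the wing and 0.127 to 0.205 in the carinated margin, against at most 0.00428 and -0.0252 for any other pairing, and each of the 12 columns of each tissue correlated best with that partner. These pairs were summed, giving 48 libraries of 8 tissues with 6 each. Which column of a pair is left stays unknown, so the planned tests of left against right, of side by tissue, and of left or right libraries alone were not run. In their place columns 1 to 6 were compared with columns 7 to 12. Deviations also showed that replicate numbers pair the libraries across the 7 tissues other than the head: in all 21 tissue pairs same-numbered libraries correlated at r = 0.129 to 0.394, and each library correlated best with its own number. Same-numbered correlations with the head ran from -0.1 to 0.0325, so the numbers do not pair the head with the others.

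Column totals ran from 12.09 to 21.41 mega-counts (M) outside the head and from 74.83 to 87.27 M in the head, a ratio of medians of 4.932. Floors and counting intervals cover counting error only, since no molecular identifiers or removal of PCR copies are described. Expected counts were rounded to whole numbers. Transcripts were kept by filterByExpr with tissue as the group (minimum count 10, minimum total count 15), which left 15239 for testing, 848 of them non-coding. Libraries were scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) in a fit of all 48 libraries with tissue as the only term. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05. The spread was shared across tissues, and replicate number was not in the model. Levels are TMM-scaled CPM, means with SD over 6 libraries unless stated. Fold changes are log2 with their standard error. Where a tissue had 0 counts in all 6 libraries, the fold is a lower bound against 3 counts over the 6 libraries. It is taken from counts summed over the libraries of each tissue and so differs somewhat from a ratio of mean CPM. For 1 to 3 counts the ratio is given with its 95% counting interval.

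The distance between a library and a tissue was the root mean squared difference of log2 CPM (prior count 2) to the tissue mean, made without the library of the same number. Differences over the 6 horn libraries were tested by a two-sided exact sign-flip permutation test with 64 flips, whose smallest p is 0.03125. The same test was used on correlations across transcripts, 1 per replicate number.

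The tests, the gene lists, the naming rule and a first set of other settings were set before the data were examined. By the rule, transcripts are named if called, at 5 CPM or more in the higher tissue and with all 6 libraries of one tissue above all 6 of the other, a separation that chance gives in 0.216% of transcripts. Up to 6 transcripts with a name other than a locus number were taken per direction in the 5 main comparisons and up to 3 in the 9 others, in order of fold change. Up to 2 transcripts per direction known only by an identifier, which the rule foresaw for a table without names, were added after it was seen that nearly all symbols were locus numbers. The other settings of this first set were DESeq2 1.42.0, RLE size factors, no filter, a filter of 1 CPM in 12 libraries, a fit of both tissues alone, a replicate block, and a test against a fold of 1.5. For distances they were the 500 most variable transcripts, 1 minus Spearman's correlation and a prior count of 0.5. For correlations and shared calls they were Spearman's rho, transcripts called in wing against head, exchanged contrast tissues and changes of at least 2-fold. For calls the block was also applied in comparisons with the head, although the numbers do not pair the head with the other tissues. Added after the data were seen were total counts with no further scaling, single column sets, the pairing of columns 2k-1 and 2k, transcripts of a gene summed, head or all libraries thinned by random draws to a common total, leaving out the head, leaving out the transcripts that set the horn apart, and leaving out each replicate number. For transcripts higher in both of 2 tissues, the libraries of the 6 other tissues were divided between the lists. Unchanged groups were also simulated 20 times, each transcript at its level in the other tissue where it was highest. Figures were drawn with Python matplotlib 3.10.9.

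The test was tried on simulated data, negative binomial counts with the mean levels, spread and totals of the real libraries and 200 transcripts changed. In the simulation of thoracic horn against dorsal prothorax (14829 transcripts), 14.9% of 1.5-fold, 29% of 2-fold and 71.9% of 4-fold changes were called, with 0 false calls among 76. In that of T2 wing against dorsal head (14883 transcripts), the percentages were 10.6, 31.2 and 58.6, with 2 false calls among 70. Changes of all 3 sizes were therefore missed in part in these simulations. The real comparisons called far more transcripts than 76 or 70, which makes the threshold on the unadjusted p less strict. The percentages therefore do not give the share missed in the real comparisons.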

Results

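Gene expression was measured by RNA sequencing in the epidermis of male Onthophagus taurus prepupae, to ask how the thoracic horn, an outgrowth of the prothorax, relates to the wing and to other parts of the body wall. The 48 libraries fell into 8 tissues of 6 libraries each: T2 wing, thoracic horn, anterior margin, posterior margin, carinated margin, dorsal prothorax, support structures of the abdomen and dorsal head. Total counts, in mega-counts (M), were 81.41 ± 4.08 M per library in the head (SD, n = 6), 33.49 ± 2.29 M in the wing and 32.81 ± 3.52 M in the carinated margin, where both sides were summed. In the other 5 tissues mean totals lay between 15.07 and 17.87 M. Low transcripts are therefore measured more precisely in the head than elsewhere, and library depth differs with tissue.

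The horn, the support structures and the dorsal head were the most distinct of the 8 tissues, and the 3 margins of the prothorax were the least. Of 15239 tested transcripts, between 4988 and 7296 differed between the horn and any other tissue. The anterior, posterior and carinated margins differed from one another in only 148 to 239 transcripts. Dorsal prothorax differed from the margins in 1180 to 1614 transcripts and from the horn in 4996. With the replicate number as a block these counts rose to 509 to 700 among the margins, 2380 to 2989 between dorsal prothorax and margins, and 6128 between dorsal prothorax and horn. These are calls of edgeR's quasi-likelihood test at an adjusted p under 0.05. Higher and lower are relative to the bulk of transcripts, and this reference matters for the horn, whose TMM factors (0.531 to 0.639) lay below those of the other tissues (0.815 to 1.42).

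**Figure D1:**
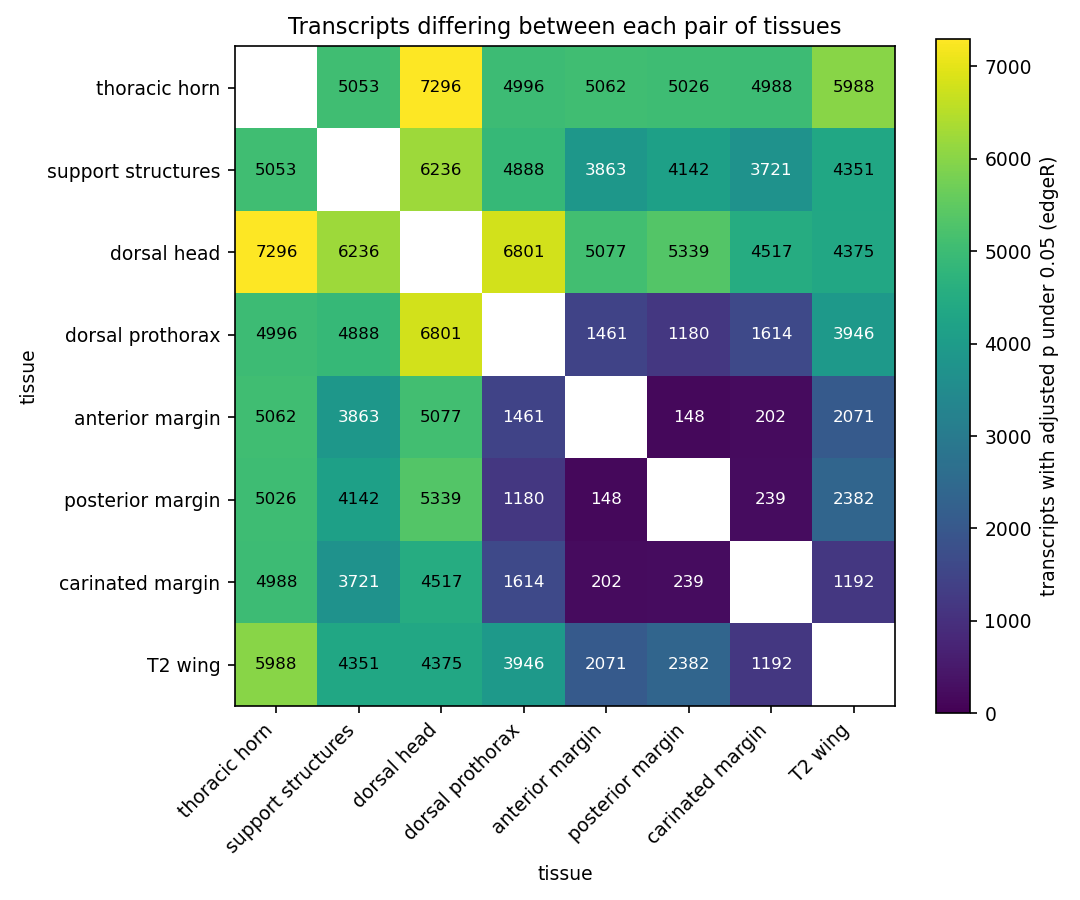
Number of transcripts (edgeR, adjusted p under 0.05, of 15239 tested) that differed between each pair of the 8 tissues, 6 libraries per tissue, with color and printed number giving the count. Pairs with the horn or the dorsal head had high counts, up to 7296, and pairs among the 3 margins had 148 to 239.

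The first question was what separates the wing from an epidermis of the thorax that is not known to be tied to wings. T2 wing and dorsal prothorax differed in 3946 transcripts, 2182 higher and 1764 lower in the wing, of which 771 and 1011 differed at least 2-fold. LOC111422534 (XM_023055738.1) stood at 53 ± 21.8 CPM in the wing (SD, n = 6) and had 0 counts in the dorsal prothorax, at least 2043-fold higher in the wing. LOC111425442 (XM_023059453.1), at 22.2 ± 5.16 CPM in the wing, was at least 844-fold higher. With the 4 and 5 tested transcripts of these genes summed, the differences were 4.64 and 6.37 log2 units (adjusted p = 5.6e-13 and 1.1e-07, edgeR). In the other direction XM_023051862.1 (no gene matched) had 0 counts in the wing and 71.6 ± 12.5 CPM in the dorsal prothorax, at least 5468-fold lower, and LOC111419103 (XM_023051863.1) was at least 3252-fold lower, with 42.8 ± 6.38 CPM in the dorsal prothorax. Of the transcripts with a gene name 3 passed the naming rule: ClpP (XM_023062255.1) was higher in the wing by 0.62 ± 0.11 log2 units (adjusted p = 1.8e-05, edgeR), RFeS (XM_023064499.1) by 0.52 ± 0.1 (adjusted p = 7.5e-05), and betaCO (XM_023064597.1) fell by 0.5 ± 0.07 (adjusted p = 1.1e-07). Of 45 tested transcripts with a gene name, 9 were called, 5 higher and 4 lower. With RLE size factors the share of calls higher in the wing was 45.3% rather than 55.3%, and with total counts it was 39.2% (median of all transcripts moved by -0.135 log2 units), so which direction prevailed depended on the scaling.

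The horn was next compared with the dorsal prothorax, the contrast tissue of its own segment. They differed in 4996 transcripts, 2044 higher and 2952 lower in the horn, with 1204 and 1516 at least 2-fold. LOC111426960 (XM_023061883.1), at 564 ± 200 CPM in the horn (SD, n = 6), and XM_023053118.1 (no gene matched), at 516 ± 196 CPM, had 0 counts in the dorsal prothorax and were at least 21322-fold and at least 19214-fold higher. Conversely LOC111421032 (XM_023054142.1), at 38.2 ± 25.3 CPM in the dorsal prothorax, and LOC111420963 (XM_023054067.1), at 14.9 ± 7.5 CPM, had 0 counts in the horn and were at least 672-fold and at least 253-fold lower. Over the 2 tested transcripts of each gene, LOC111426960 was higher by only 2.9 log2 units (adjusted p = 0.00015, edgeR) and LOC111421032 changed by -4.88 (adjusted p = 1.9e-08).

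Among transcripts with a gene name, IT (XM_023046538.1) was higher in the horn than in the dorsal prothorax by 3.8 ± 0.53 log2 units (adjusted p = 2e-07, edgeR), with 17.1 ± 7.1 against 1.22 ± 0.695 CPM. REPTOR-B (XM_023061826.1) was higher by 2.15 ± 0.29 (adjusted p = 9.9e-08). RFeS (XM_023064499.1) was higher by 1.08 ± 0.1 and S1 (XM_023049042.1) by 0.96 ± 0.1, but with total counts both changed sign, to -0.03 and -0.13. ND-AC (XM_023060797.1) fell by 1 ± 0.1 (adjusted p = 2.8e-10), PNK (XM_023060472.1) by 0.57 ± 0.09 and betaCO (XM_023064597.1) by 0.36 ± 0.07. Of the 45 tested transcripts with a gene name 8 were higher and 10 lower. Scaled by total counts, 9610 transcripts were called and 6.99% of them were higher in the horn, against 40.9% in the TMM fit, with the median of all transcripts moved by -1.1 log2 units. In a fit of these tissues alone the count was 2867, with 1493 higher and 1374 lower, so the excess of lower calls was not kept.

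Horn and wing differed in 5988 transcripts with TMM scaling, more than horn and dorsal prothorax, an order that total counts reversed (8683 against 9610). Of the 5988, 2395 were higher and 3593 lower in the horn, with 1561 and 1987 at least 2-fold. LOC111420100 (XM_023053048.1) took 83400 ± 10400 CPM in the horn (SD, n = 6) against 0.0455 ± 0.0508 CPM in the wing, and LOC111418544 (XM_023051091.1) took 29900 ± 4640 against 0.0295 ± 0.0491 CPM. Only 10 and 6 counts over all wing libraries lie behind these low values. The wing transcripts LOC111425442 (XM_023059453.1) and LOC111425424 (XM_023059423.1), at 22.2 ± 5.16 and 18.6 ± 5.97 CPM, had 0 counts in the horn and were at least 400-fold and at least 328-fold lower there. With the transcripts of each gene summed they changed by -7.46 and -6.35 log2 units. REPTOR-B (XM_023061826.1) was higher in the horn by 1.64 ± 0.28 log2 units (adjusted p = 7.3e-06, edgeR), S1 (XM_023049042.1) by 1.13 ± 0.1 and RFeS (XM_023064499.1) by 0.56 ± 0.1. With total counts the first 2 were not called, at 0.66 (adjusted p = 0.066) and 0.17 (adjusted p = 0.23), and RFeS turned to -0.41. CRM (XM_023059892.1) fell by 1.78 ± 0.25 (adjusted p = 1.9e-07), ND-AC (XM_023060797.1) by 1.26 ± 0.11, ClpP (XM_023062255.1) by 0.57 ± 0.11 and PNK (XM_023060472.1) by 0.55 ± 0.09. The share of calls higher in the horn was 40% with TMM, 50.2% with RLE size factors and 9.46% with total counts, which moved the median of all transcripts by 0.149 and -0.967 log2 units.

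The dorsal head served as a contrast outside the thorax. Horn and head differed in 7296 transcripts, the highest count of the 28 tissue pairs with TMM but not with total counts (8194), 2910 higher and 4386 lower in the horn. LOC111418568 (XM_023051107.1) had 3600 ± 2560 CPM in the horn (SD, n = 6) and 0.0168 ± 0.0114 in the head, and LOC111418544 (XM_023051091.1) had 29900 ± 4640 and 0.259 ± 0.0926 CPM. LOC111417757 (XM_023050128.1) and LOC111424387 (XM_023057893.1), at 8.25 ± 2.85 and 6.92 ± 1.88 CPM in the head, had 0 counts in the horn and were at least 149-fold and at least 125-fold lower. For LOC111417757 this held for the transcript but not for the gene, whose summed transcripts changed by 0.28 (adjusted p = 0.069). S1 (XM_023049042.1) was higher in the horn by 1.43 ± 0.1 log2 units (adjusted p = 1e-15, edgeR), REPTOR-B (XM_023061826.1) by 1.12 ± 0.28, Rab3-GA (XM_023062064.1) by 1 ± 0.15, SWI (XM_023045486.1) by 0.65 ± 0.22 and SREB (XM_023050987.1) by 0.35 ± 0.13. With total counts REPTOR-B and SWI were not called (adjusted p = 0.18 and 0.87) and SREB turned to -0.24. CRM (XM_023059892.1) fell by 2.05 ± 0.25, UG (XM_023053981.1) by 1.89 ± 0.74 and the ND-AC transcripts XM_023060798.1 and XM_023060797.1 by 1.73 ± 0.2 and 1.6 ± 0.11. UG was not called with RLE size factors (adjusted p = 0.056). zetaCO (XM_023047775.1) fell by 1.04 ± 0.13 and epsilonCO (XM_023045054.1) by 0.97 ± 0.09. The share of calls higher in the horn was 39.9% with TMM, 49.5% with RLE size factors and 18.5% with total counts, with the median moved by 0.194 and -0.602 log2 units.

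T2 wing and dorsal head differed in 4375 transcripts, 1864 higher and 2511 lower in the wing. LOC111419112 (XM_023051873.1), at 6.64 ± 1.04 CPM in the wing (SD, n = 6), had 0 counts in the head and was at least 949-fold higher, and XM_023053673.1 (no gene matched) had 6.41 ± 4.61 CPM in the wing against 0.0283 ± 0.0164. LOC111424359 (XM_023057866.1) and LOC111424387 (XM_023057893.1) had 0 counts in the wing and were at least 808-fold and at least 531-fold lower. Named transcripts that passed the rule were all lower in the wing: CNB (XM_023058115.1) fell by 1.34 ± 0.19 log2 units (adjusted p = 6.7e-07, edgeR), epsilonCO (XM_023045054.1) by 0.9 ± 0.09, TORI (XM_023045797.1) by 0.84 ± 0.14, zetaCO (XM_023047775.1) by 0.79 ± 0.13, RFeS (XM_023064499.1) by 0.69 ± 0.1 and Apep (XM_023046489.1) by 0.46 ± 0.07. Apep was not called with total counts (adjusted p = 0.51). Dorsal prothorax and dorsal head, both contrast tissues, differed in 6801 transcripts, 2961 higher and 3840 lower in the prothorax. LOC111427676 (XM_023062900.1) and LOC111419103 (XM_023051863.1) were higher in the prothorax, at 24.1 ± 11.6 against 0.0833 ± 0.204 CPM and 42.8 ± 6.38 against 0.197 ± 0.267 CPM. LOC111414410 (XM_023045749.1) and LOC111422534 (XM_023055738.1) had 0 counts in the prothorax and were at least 610-fold and at least 397-fold lower. All 32 head counts of XM_023062900.1 lay in a single library. With the transcripts of a gene summed, LOC111427676 changed by 1.94 and LOC111422534 by -3.52 log2 units. Rab3-GA (XM_023062064.1) was higher in the prothorax by 0.87 ± 0.15, SWI (XM_023045486.1) by 0.84 ± 0.21 and betaCO (XM_023064597.1) by 0.66 ± 0.07, whereas UG (XM_023053981.1) fell by 1.83 ± 0.73, RFeS (XM_023064499.1) by 1.21 ± 0.1 and CNB (XM_023058115.1) by 1.15 ± 0.19. UG lost its call with RLE size factors (adjusted p = 0.057), with total counts (adjusted p = 0.14) and with columns 1 to 6 of the summed tissues alone (adjusted p = 0.05), and changed by -0.66 with the transcripts of its gene summed. Total counts raised the share of calls higher than in the head from 42.6% to 74.4% for the wing and from 43.5% to 72.8% for the prothorax, with the median moved by 0.365 and 0.499 log2 units. RLE size factors gave 51.1% for the prothorax (median moved by 0.132). Head libraries did not share replicate structure or depth with the other tissues, so tissue and batch cannot be told apart in any comparison with the head.

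Horn and margins of the prothorax were compared next. The horn differed from the carinated margin in 4988 transcripts (1770 higher, 3218 lower), from the anterior margin in 5062 (2032 higher, 3030 lower) and from the posterior margin in 5026 (2000 higher, 3026 lower). S1 (XM_023049042.1) was higher in the horn than in each margin, by 1.38 ± 0.1, 1.3 ± 0.1 and 1.29 ± 0.1 log2 units (adjusted p = 5.8e-15, 2.8e-14 and 3.5e-14, edgeR), and ND-AC (XM_023060797.1) fell by 0.96 ± 0.1, 0.94 ± 0.1 and 0.93 ± 0.1. LOC111418568 (XM_023051107.1) had 3600 ± 2560 CPM in the horn (SD, n = 6) and 0.0563 ± 0.0394 in the carinated margin, LOC111420100 (XM_023053048.1) had 83400 ± 10400 and 2.31 ± 1.38, and LOC111418544 (XM_023051091.1) had 29900 ± 4640 in the horn and 5.33 ± 6.76 in the anterior margin. XM_023053118.1 (no gene matched) had 516 ± 196 CPM in the horn and 0.06 ± 0.147 in the anterior margin, where all 9 counts lay in a single library. It had 0 counts in the posterior margin and was at least 19972-fold higher in the horn than there. LOC111426960 (XM_023061883.1) also had 0 counts in the posterior margin and was at least 22162-fold higher in the horn, but by 3.35 log2 units with its 2 tested transcripts summed. In the other direction XM_023048989.1 (no gene matched) had 0 counts in the horn and was at least 526-fold, 455-fold and 649-fold lower there than in the carinated, anterior and posterior margin. XM_023058657.1 (no gene matched) was at least 777-fold lower than in the carinated margin and LOC111420963 (XM_023054067.1) at least 716-fold lower than in the posterior margin. LOC111418839 (XM_023051526.1), at least 362-fold lower than in the anterior margin, was not called when its 3 tested transcripts were summed (-0.46, adjusted p = 0.21).

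REPTOR-B (XM_023061826.1) was higher in the horn than in the carinated margin by 1.29 ± 0.28 log2 units (adjusted p = 0.00029, edgeR) and than in the anterior margin by 1.06 ± 0.28 (adjusted p = 0.0025), and with total counts neither was called, at 0.42 and 0.01. IT (XM_023046538.1) was higher than in the anterior margin by 2.63 ± 0.5. RFeS (XM_023064499.1) was higher than in the carinated and posterior margins by 0.67 ± 0.1 and 0.74 ± 0.1, and with total counts it turned to -0.17 and -0.22. CRM (XM_023059892.1) fell by 1.5 ± 0.25 against the carinated margin. PNK (XM_023060472.1) fell by 0.57 ± 0.09 against the posterior margin and by 0.34 ± 0.09 against the anterior margin, a call that DESeq2 did not make (adjusted p = 0.1). With total counts the counts rose to 8323, 8914 and 8775 for the carinated, anterior and posterior margin, and the share higher in the horn dropped from 35.5%, 40.1% and 39.8% to 6.63%, 6.73% and 7.48%, the median moving by -0.84, -1 and -0.944 log2 units. RLE size factors gave 46.7% for the carinated margin (median moved by 0.126), 47.9% for the anterior and 47.6% for the posterior margin. In fits of 2 tissues alone 3822 transcripts were called for the carinated margin (1781 higher, 2041 lower), 3367 for the anterior (1662 higher, 1705 lower) and 3173 for the posterior margin (1528 higher, 1645 lower), so most of the excess of lower calls depended on scaling and fit.

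Against the support structures the horn differed in 5053 transcripts, 1931 higher and 3122 lower. XM_023051862.1 and XM_023064072.1 (no gene matched), at 51.2 ± 8.74 and 24.3 ± 16.1 CPM in the horn (SD, n = 6), had 0 counts in the support structures and were at least 1938-fold and at least 912-fold higher. XM_023060367.1 (no gene matched) had 0 counts in the horn and was at least 2003-fold lower, and XM_023051097.1 (no gene matched), with 3 counts in the horn, was lower by a ratio of 18400 (95% counting interval 6310 to 89400). IT (XM_023046538.1) was higher in the horn by 2.75 ± 0.5 log2 units (adjusted p = 2.6e-05, edgeR), CNB (XM_023058115.1) by 1.08 ± 0.19 and S1 (XM_023049042.1) by 0.69 ± 0.1. MR (XM_023044477.1) fell by 3.46 ± 0.84 (adjusted p = 0.001), from 120 ± 44.9 CPM in the support structures to 10.9 ± 13.5 in the horn, though the 6 tested transcripts of its gene together changed by -1.43, MSB (XM_023058788.1) by 1.89 ± 0.13 and ND-AC (XM_023060797.1) by 0.72 ± 0.1. With total counts 8712 transcripts were called and 6.37% were higher in the horn, against 38.2%, the median moved by -0.869 log2 units, CNB was not called (adjusted p = 0.41) and S1 turned to -0.18.

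When the margins and the support structures were set against the wing, the carinated margin differed least and the support structures most. The carinated margin differed from the wing in 1192 transcripts (732 higher, 460 lower), the anterior margin in 2071 (1077 higher, 994 lower), the posterior margin in 2382 (1140 higher, 1242 lower) and the support structures in 4351 (2154 higher, 2197 lower). At least 2-fold higher and lower were 508 and 157, 633 and 321, 675 and 416, and 1643 and 759 in the same order. XM_023051862.1 (no gene matched) had 0 counts in the wing and was at least 4377-fold, 4944-fold and 3039-fold higher in the carinated, anterior and posterior margin. LOC111414917 (XM_023046385.1) was at least 7511-fold higher in the anterior and at least 10355-fold higher in the posterior margin, at 93.2 ± 36.6 and 135 ± 49.1 CPM (SD, n = 6), and XM_023058657.1 (no gene matched) at least 3308-fold higher in the carinated margin. LOC111422534 (XM_023055738.1) and XM_023047166.1 (no gene matched) had 0 counts in the anterior margin and were at least 2105-fold and at least 800-fold lower than in the wing. For LOC111422534 the summed transcripts of the gene did not differ (0.11, adjusted p = 0.88). LOC111425442 (XM_023059453.1) was at least 877-fold lower in the posterior margin, and its summed transcripts changed by -5.34 log2 units. XM_023055264.1 (no gene matched), at 68.5 ± 61.4 CPM in the wing, stood at 0.553 ± 0.797 in the carinated and 0.156 ± 0.318 in the posterior margin, and XM_023054939.1 (no gene matched), at 5.48 ± 3.28 CPM in the wing, at 0.0248 ± 0.013 in the carinated margin.

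betaCO (XM_023064597.1) was higher than in the wing in all 3 margins, by 0.24 ± 0.07, 0.26 ± 0.07 and 0.28 ± 0.07 log2 units in the carinated, anterior and posterior margin (adjusted p = 0.012, 0.005 and 0.0015, edgeR), though with total counts it was not called in the carinated margin (adjusted p = 0.49). CNB (XM_023058115.1) was higher in the carinated margin by 0.74 ± 0.19 and Apep (XM_023046489.1) in the posterior margin by 0.31 ± 0.07. In the support structures LOC111428488 (XM_023064026.1) reached 13100 ± 2420 CPM (SD, n = 6) against 0.28 ± 0.202 in the wing, and LOC111418544 (XM_023051091.1) 993 ± 468 against 0.0295 ± 0.0491. MR (XM_023044477.1) was higher there than in the wing by 4.06 ± 0.86 (adjusted p = 0.00023, and 1.7 log2 units over all transcripts of its gene), MSB (XM_023058788.1) by 1.84 ± 0.13 and REPTOR-B (XM_023061826.1) by 1.79 ± 0.28. CRM (XM_023059892.1) fell by 1.58 ± 0.25, alphaCO (XM_023058960.1) by 0.66 ± 0.15 and ND-AC (XM_023060797.1) by 0.54 ± 0.1, LOC111425424 (XM_023059423.1) was at least 696-fold lower (-5.69 log2 units with its transcripts summed), and LOC111420652 (XM_023053690.1), with 1 count in the support structures, was lower by a ratio of 6460 (95% counting interval 1160 to 255000). With the replicate number as a block the counts against the wing rose to 2496, 3469 and 3765 for the carinated, anterior and posterior margin. Without replicate 5 or replicate 6 the count for the carinated margin was 774 or 787, and without replicate 6 that for the posterior margin was 1560. DESeq2 called 1810 transcripts for the carinated margin, and a fit of both tissues alone 1906, of which 951 were higher and 955 lower. RLE size factors moved the share higher in the support structures from 49.5% to 60.3%, with the median moved by 0.11 log2 units. Total counts moved it the other way, to 1868 higher and 2557 lower. The anterior margin turned with the block, to 1709 higher and 1760 lower. For the posterior margin the prevailing direction turned, with 47.9% of calls higher as reported, 56.2% with RLE size factors (1261 higher, 982 lower) and 52.9% with DESeq2 (1551 higher, 1379 lower). Total counts moved that in the carinated margin from 61.4% to 41.3% and that in the anterior margin from 52% to 62.5%.

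Over all tested transcripts and with TMM scaling the horn lay closer to the other prothoracic tissues than to the wing, the head or the support structures. Its distance was 2.022 ± 0.0273 log2 units to the anterior margin (SD, n = 6), 2.036 ± 0.0406 to the posterior margin, 2.04 ± 0.0425 to the dorsal prothorax and 2.075 ± 0.037 to the carinated margin. It was 2.154 ± 0.0311 to the wing, 2.18 ± 0.0552 to the head and 2.214 ± 0.0573 to the support structures. Horn libraries lay 1.619 ± 0.036 from others of their own tissue. In 6 of 6 horn libraries the wing was farther than each of the other 4 prothoracic tissues and nearer than the support structures (exact sign-flip permutation test, two-sided, p = 0.03125 each, the smallest possible, adjusted p = 0.0375 over 6 comparisons). Wing and head did not differ in distance (wing minus head -0.02614 ± 0.0368, exact p = 0.156, wing farther in 2 of 6). Each tissue mean left out only the library of the same number, so the 6 differences share most libraries of the other tissues. The p of these distance tests therefore covers the spread of the horn libraries but not that of the other tissues. The horn distance to T2 wing minus horn distance to dorsal head changed sign over the 500 most variable transcripts (0.5902), with total counts (0.1196) and without replicate 3 (0.01089). With total counts the head, at 2.14, was nearer to the horn than the carinated margin (2.152) and the dorsal prothorax (2.182). Over the 500 most variable transcripts the head, at 4.556, came before the dorsal prothorax (4.561), the posterior margin (4.611) and the carinated margin (4.656). The anterior margin was nearest there, at 4.407. The horn distance to T2 wing minus horn distance to support structures was no longer below 0 in 6 of 6 libraries over the 500 most variable transcripts (exact p = 0.344). The horn distance to T2 wing minus horn distance to carinated margin was above 0 in 5 of 6 without transcripts that set the horn apart (exact p = 0.0625). The wing itself was closest to the carinated margin in 6 of 6 libraries, at 1.353 ± 0.0252, and farthest from the horn, at 1.912 ± 0.0265. This was not particular to the wing. The horn was also the farthest tissue from the head (1.914), the support structures (2.103) and the carinated margin (1.845). From the dorsal prothorax and the anterior and posterior margins the support structures were farthest.

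**Figure D2:**
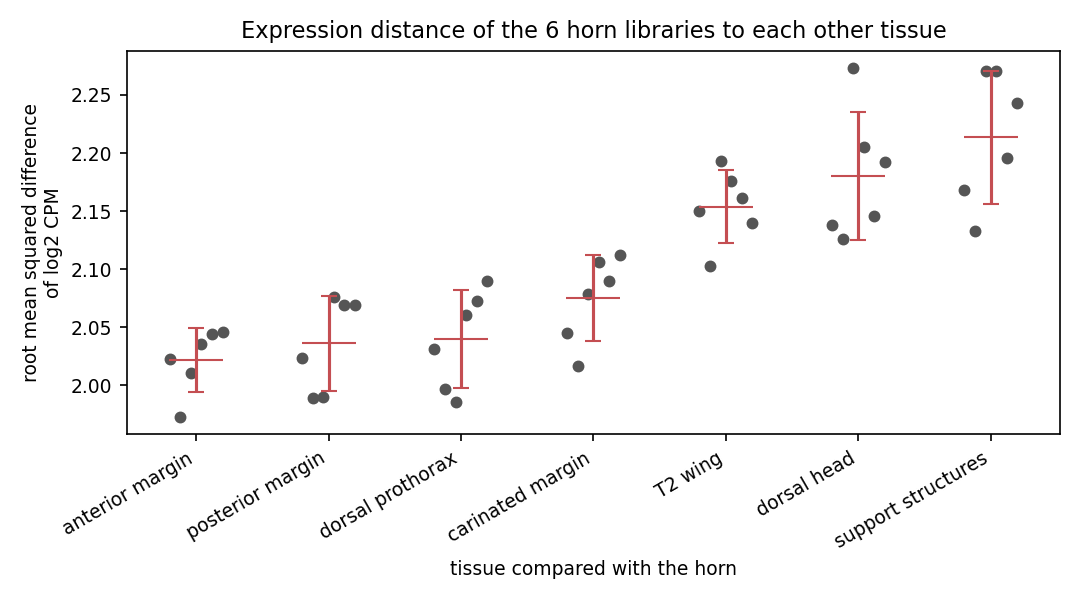
Expression distance (root mean squared difference of log2 CPM, vertical axis, not starting at 0) of each of the 6 horn libraries (points) to the mean of each other tissue (horizontal axis), with mean and SD in red. The other 4 prothoracic tissues lie at means of 2.022 to 2.075, below the wing at 2.154, the head at 2.18 and the support structures at 2.214.

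To ask whether what separates the wing from a contrast tissue also separates the horn or another tissue from a contrast tissue, wing minus head was compared with each tissue minus dorsal prothorax, so that no library was shared. Across the 15239 transcripts, which are not independent replicates, the fold changes were weakly and negatively correlated for every tissue tried. Pearson's r was -0.0793 for the horn, -0.136 for the anterior margin, -0.108 for the posterior margin, -0.125 for the carinated margin and -0.192 for the support structures, with an SD over leaving out each replicate number of 0.00608 to 0.0167. Spearman's rho was -0.116, -0.236, -0.235, -0.256 and -0.217. Correlations computed per replicate were below 0 in 6 of 6 replicates for all 5 tissues (exact sign-flip permutation test, p = 0.03125, adjusted p = 0.03125). Each used wing minus head fitted without that replicate, so the 6 values share most wing and head libraries. All 5 tissues also share the dorsal prothorax libraries. The p therefore does not cover the spread of wing and head, and the 5 tissues are not separate tests. Horn and margins were not told apart by this measure (adjusted exact p = 0.3749 to 0.5625). Against the support structures r was higher in the horn by 0.0615 ± 0.0289, in 6 of 6 replicates (exact p = 0.03125, adjusted p = 0.125 over 4 comparisons). With 6 replicates a single difference among 4 cannot reach a lower adjusted p. With both contrast tissues exchanged, wing minus dorsal prothorax against each tissue minus head, r was -0.208 for the horn, -0.282, -0.324 and -0.256 for the anterior, posterior and carinated margin and -0.15 for the support structures. The order of horn and support structures was thereby reversed, so no difference between them is claimed.

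Calls in the same direction in both contrasts numbered 765 for the horn, 195 higher and 570 lower, where independent lists would share 736.4 (250 higher and 486.4 lower). Opposite calls numbered 1316, against 697.9 for independent lists. For the other tissues same-direction calls were also near the number for independent lists and opposite calls above it. Same-direction calls were 188 for the anterior margin (205.3 for independent lists), 164 for the posterior margin (166.2), 215 for the carinated margin (223.5) and 682 for the support structures (692.4). In the support structures, as in the horn, fewer were higher (239, against 325.5) and more lower (443, against 367) than in independent lists, while opposite calls were 583, 475, 610 and 1432 (against 214.1, 172.6, 239.8 and 710.9). With the replicate number as a block the same-direction calls of the anterior, posterior and carinated margin were 376, 370 and 433, against 471.2, 406.6 and 501.9 for independent lists. Those of the horn and the support structures were 1073 and 1001, against 1095 and 1057. The horn count thus lay slightly below rather than above that of independent lists. Wing against head is part of these counts, and the replicate numbers do not pair the head with the wing. Among changes of at least 2-fold, same-direction calls lay above the number for independent lists in all 5 tissues: 227 for the horn (190.9), 96 for the anterior margin (48.85), 89 for the posterior margin (42.13), 102 for the carinated margin (45.27) and 231 for the support structures (187.2). Opposite calls were again more frequent, at 481, 202, 172, 186 and 628. With both contrast tissues exchanged, 415 same-direction calls were shared by wing against dorsal prothorax and horn against dorsal head, where independent lists would share 924.4, and opposite calls numbered 2333 (964.9 for independent lists). This shortfall was common to all tissues, with 250, 224, 239 and 573 same-direction calls for the anterior, posterior and carinated margin and the support structures (648.7, 681.5, 579 and 803.2 for independent lists).

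Finally transcripts were counted that set a single tissue apart, called in the same direction against all 7 other tissues. The horn had 477 such transcripts that were higher and 1012 that were lower, the head 1083 and 683, the support structures 625 and 288, the dorsal prothorax 115 and 103 and the wing 55 and 143. The carinated margin had 8 and 1, the anterior margin 5 and 3 and the posterior margin 4 and 2. The 477 transcripts higher in the horn took 47.6% ± 0.623 of all horn counts (SD, n = 6) and 24.7% to 29.1% of those elsewhere. LOC111420100 (XM_023053048.1) alone took 47900 ± 4090 CPM of the unscaled horn total, LOC111428486 (XM_023064023.1) 42400 ± 3000, LOC111418349 (XM_023050869.1) 41800 ± 5120, LOC111418555 (XM_023051100.1) 33400 ± 6200 and LOC111428488 (XM_023064026.1) 22600 ± 2050. LOC111418349 was abundant in every tissue (26300 to 41800), whereas the other 4 stayed at or below 1250 in the 6 tissues other than horn and support structures. Together these 5 transcripts took 18.8% ± 1.37 of horn counts. Of the 477, 258 also held a larger share of unscaled counts than in each other tissue. All 1012 lower ones held a smaller share, but the scaling all but fixed this. Horn TMM factors lay below those of every other tissue, so a transcript lower after scaling is lower still without it. With total counts 99 were higher and 4916 lower. Set-apart counts of the other tissues moved as well. Each includes a comparison with the head, which the replicate numbers do not pair, so the block values below rest partly on a pairing not seen. With the replicate number as a block, higher and lower were 715 and 1204 for the horn, 1431 and 772 for the head, 759 and 450 for the support structures, 256 and 197 for the dorsal prothorax, 125 and 221 for the wing, 11 and 2 for the carinated, 15 and 6 for the anterior and 14 and 14 for the posterior margin. DESeq2 gave 180 and 126 for the dorsal prothorax, 90 and 190 for the wing, 6 and 18 for the anterior and 11 and 18 for the posterior margin. With total counts they were 404 and 656 for the head, 694 and 100 for the support structures, 294 and 38 for the dorsal prothorax and 83 and 87 for the wing.

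**Figure D3:**
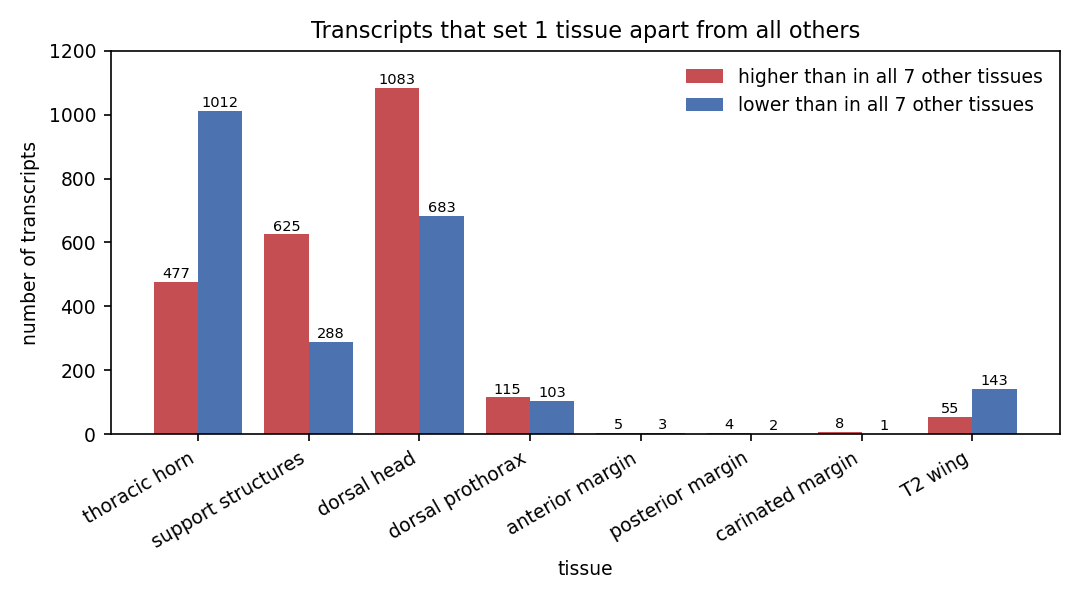
Number of transcripts (vertical axis) called higher (red) or lower (blue) in a tissue than in all 7 other tissues, 6 libraries per tissue, edgeR with TMM scaling. Head, horn and support structures had 1083, 477 and 625 higher transcripts, the 3 margins between 4 and 8, and with total counts the horn bars would stand at 99 and 4916.

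The small sets of the margins and of horn with wing are named here, a choice made after their values were seen. The carinated margin had 8 transcripts higher than in every other tissue, among them LOC111416848 (XM_023048953.1) at 83.1 ± 13.3 CPM (SD, n = 6) against at most 6.58 elsewhere, LOC111420527 (XM_023053543.1) at 81.9 ± 9.3 against at most 17.5 and LOC111416850 (XM_023048954.1) at 45.3 ± 6.36 against at most 1.22. Its only lower transcript was LOC111427810 (XM_023063128.1), at 1.43 ± 0.594 against 2.85 to 22.8 CPM. The anterior margin was higher in LOC111424976 (XM_023058715.1, 121 ± 24.1 against at most 97.6 CPM), XM_023050448.1 (52.8 ± 22.5 against at most 3.69), XM_023044591.1 (9.66 ± 5.06 against at most 0.972), LOC111419119 (XM_023051884.1, 3.86 ± 2.23) and LOC111428282 (XM_023063741.1, 3.76 ± 2), and lower in XM_023047166.1, XM_023047167.1 (both with 0 counts) and LOC111429107 (XM_023064916.1, 6.69 ± 1.12). The posterior margin was higher in XM_023049181.1 (1100 ± 192 against at most 637 CPM), LOC111413261 (XM_023044165.1, 87.9 ± 18.1), LOC111427293 (XM_023062354.1, 56.1 ± 8.73) and LOC111420766 (XM_023053813.1, 18.9 ± 11.8), and lower in LOC111413453 (XM_023044433.1, 1170 ± 308 against at least 2160) and LOC111424322 (XM_023057822.1, 176 ± 11.6 against at least 287). Transcripts higher in both horn and wing than in each of the 6 other tissues numbered 3, where independent lists would share 1.9. These were LOC111419617 (XM_023052443.1, 2700 ± 489 CPM in the horn, 2450 ± 147 in the wing and at most 1830 elsewhere), LOC111426935 (XM_023061843.1, 670 ± 154 and 614 ± 77.1, at most 198 elsewhere) and LOC111426179 (XM_023060575.1, 15.1 ± 1.85 and 15.4 ± 1.66, at most 12.8 elsewhere).

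A comparison within a tissue gave the background. Columns 1 to 6 and columns 7 to 12 of the same tissue, which come from the same 6 individuals, did not differ in any transcript by edgeR with the individual as a block. In the wing 0 of 11883 transcripts were called, 603 had an unadjusted p under 0.05 (594.2 would by chance), and the lowest adjusted p was 0.769. In the carinated margin 0 of 11970 were called, 361 had an unadjusted p under 0.05 (598.5 would by chance), and the lowest adjusted p was 1. DESeq2 called 48 transcripts in the wing and 26 in the carinated margin. Whether these column sets are left and right is not known, so left and right were not compared.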

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

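The quantities tried here were chosen after the data were seen, and the criterion was set beforehand: a library stood out if its gap to the nearest other library of the tissue exceeded Dixon's critical share of the range for 6 samples. Of 175 groups tried 10 had such a library, and chance picks about 1 in 20 groups, here 8.75, so their number is close to that of chance. No biological explanation was tested for any of them.

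In the horn, replicate 3 lay 1.69 log2 units from the other horn libraries, with the next at 1.61. In the posterior margin, replicate 4 lay 1.61 from the others (next 1.41), and its 10 most abundant transcripts took 44.6% of counts (next 42%). LOC111418544 (XM_023051091.1) stood at 109 CPM in replicate 2 of the support structures, where the next lowest library had 989, and at 18.8 CPM in replicate 3 of the anterior margin, where the next highest had 5.54. XM_023053673.1 reached 15.1 CPM in replicate 4 of the wing (next 7.02), and XM_023047166.1 only 5.48 CPM in replicate 2 of the wing (next 19). MSB (XM_023058788.1) reached 61.1 CPM in replicate 2 of the horn (next 50.1). alphaCO (XM_023058960.1) was highest in replicate 5 of both the support structures, at 54.2 CPM (next 44.4), and the wing, at 82.6 CPM (next 68.5).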

How the results depend on the processing

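Total counts, genes summed, thinning, single column sets, the pairing of columns 2k-1 and 2k, fits without the head, leaving out replicates, leaving out transcripts that set the horn apart, RLE size factors for the sets apart, dividing control libraries between lists, and all settings for columns 1 to 6 against 7 to 12 were chosen after the data were seen. Of 468 alternative values for the main results, 416 were rated the same, 32 weaker, 17 stronger and 3 reversed. Counts were rated the same within 1.5 times the reported count, whatever the share of calls in each direction. A turn of the prevailing direction, as in wing against dorsal prothorax with RLE size factors, is therefore not seen in this tally. Distances and correlations were the same if they kept their sign and their side of the threshold. Distances without a replicate were rated by sign alone. Of 972 other values these numbers were 910, 31, 22 and 9. Left or right libraries alone, and all gene list settings, could not be run. In simulated data 14.9% and 10.6% of 1.5-fold, 29% and 31.2% of 2-fold and 71.9% and 58.6% of 4-fold changes were called, so changes of each size were missed. Except where stated, the cause was not tested.

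Tested against a fold of 1.5, which is stricter by construction, the counts were 1164 for wing against dorsal prothorax and 1517 for wing against head. For the horn they were 2175 against dorsal prothorax, 3114 against wing, 4708 against head, 2267 against carinated margin, 2287 against anterior margin, 2350 against posterior margin and 2709 against support structures. Against the wing they were 414 for the carinated margin, 717 for the posterior margin, 604 for the anterior margin and 1966 for the support structures, and 3797 for dorsal prothorax against head. With total counts the horn differed in 9610 transcripts from dorsal prothorax, 8323 from carinated margin, 8914 from anterior margin, 8775 from posterior margin and 8712 from support structures, and was set apart by 99 higher and 4916 lower transcripts. With both tissues alone in the fit the horn differed in 2867 transcripts from dorsal prothorax, 3367 from anterior margin and 3173 from posterior margin, and the carinated margin in 1906 from the wing. DESeq2 called 1810 for the latter, and 48 and 26 between column sets of the wing and the carinated margin.

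The replicate number as a block uses the pairing of libraries outside the head. With it the counts against the wing were 2496 for the carinated, 3765 for the posterior and 3469 for the anterior margin. Same-direction calls shared with wing against head were 433, 370 and 376, though the numbers do not pair the head with the wing. Among changes of at least 2-fold, fewer by construction, shared calls were 227 for the horn, 96 for the anterior, 89 for the posterior and 102 for the carinated margin and 231 for the support structures, and the horn was set apart by 242 higher and 424 lower transcripts. With contrast tissues exchanged the horn shared 415. Leaving out a replicate number gave 774 to 1097 calls for the carinated margin against the wing (774 without replicate 5, 787 without replicate 6) and 1560 to 2450 for the posterior margin (1560 without replicate 6).

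The horn distance to T2 wing minus horn distance to dorsal head, -0.02614 as reported, was 0.5902 over the 500 most variable transcripts, 0.1196 with total counts, -0.06842 without transcripts that set the horn apart, and -0.05183 to 0.01089 without each replicate (0.01089 without replicate 3). The horn distance to T2 wing minus horn distance to support structures was -0.1117 over the 500 most variable transcripts (exact p = 0.344), and the horn distance to T2 wing minus horn distance to carinated margin was 0.05012 without transcripts that set the horn apart (exact p = 0.0625). Over transcripts called in wing against head the correlation for the posterior margin was -0.188 (exact p = 0.0625).

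Named transcripts kept direction and call in 126 of 127 values with DESeq2, 125 with RLE size factors, 127 with the block, 110 with total counts, and 103 of 106 with genes summed. With total counts RFeS (XM_023064499.1) turned to -0.03, -0.41, -0.17 and -0.22 in the horn against dorsal prothorax, wing, carinated margin and posterior margin. S1 (XM_023049042.1) turned to -0.13 and -0.18 against dorsal prothorax and support structures, and SREB (XM_023050987.1) to -0.24 against head. With genes summed LOC111417757 (XM_023050128.1) changed by 0.28 in horn against head and LOC111422534 (XM_023055738.1) by 0.11 in anterior margin against wing.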

Other observations

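The tests of a separate head batch, of RNA carried over between libraries and of the choice of scaling were chosen only after the results they address were seen. The patterns below were noticed in the same data they were tested on, so any reading of them is a hypothesis.

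The horn was set apart from all 7 other tissues by 477 higher and 1012 lower transcripts. Leaving out the 477 and scaling anew kept 4303 of 4516 other calls against dorsal prothorax (95.3%), with horn TMM factors of 0.686 to 0.82. TMM itself trims transcripts of extreme level or ratio, so most calls were likely to be kept. The refit therefore cannot decide whether a few abundant transcripts caused those calls. With total counts 9610 were called against dorsal prothorax, 6.99% of them higher in the horn, against 4996 and 40.9% with TMM. With all libraries thinned to 13.11 mega-counts (M), 505 higher and 850 lower transcripts still set the horn apart, 465 and 836 of them as reported. This argues against differing library totals as the cause. Thinning did not equalize the depth left to the other transcripts, since the 477 took 47.6% of horn counts and at most 29.1% elsewhere. The horn differed from dorsal prothorax in 4.33 times as many thinned transcripts as the posterior margin did (4763 against 1099), a ratio that thinning could hardly move because totals were alike in these tissues (15.48, 15.07 and 17.48 M). With transcripts of each matched gene summed the percentage called against dorsal prothorax was 39.8 rather than 32.8 (121% of it). The horn was then set apart by 601 higher and 891 lower genes or unmatched transcripts. This argues against the division of reads between isoforms as the main cause. Transcripts without a matched gene were not summed (15104 of 23725 matched), so for these it stays open. The number of higher transcripts does depend on the scaling, since 20.8% of the 477 were called higher in all 7 comparisons with total counts. A lower RNA diversity in the horn may be part of the pattern, as 13561 ± 200 transcripts (SD, n = 6) were detected in thinned horn libraries against means of 14934 to 15936 in the other tissues. Detection also falls where abundant transcripts take more of the counts, so the cause of this difference and which scaling is right stay open.

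Calls against the dorsal head were many, 4375 for the wing and 7296 for the horn. Thinning the head libraries to 16.66 M, the median of the other columns, left 4212 for the wing, a ratio of 1.04. The wing libraries are summed pairs of columns and so remained deeper, and with every library thinned to 13.11 M the count was 3998, which argues against depth as the cause of most of these calls. Same-numbered deviations of the head and other tissues correlated at no more than 0.0325, against a mean of 0.231 among the other 7 tissues. With libraries of another number head libraries reached r = 0.155 at most. The highest mean r of a head library with any number was 0.113, against 0.16 to 0.328 for libraries of other tissues with their own number. The same individuals under other numbers were thus not seen in the head but are not excluded. Head libraries may also come from other individuals or another batch, and a batch and the tissue cannot be told apart because no other tissue shares it.

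Transcripts higher in both the horn and the support structures than in each of the 6 other tissues numbered 189, where independent sets would share 38. This was the highest count of the 28 tissue pairs, but such counts grow with the length of the lists. The number for independent sets was worked out only for the horn with the support structures, the head and the wing. The ranking therefore does not show that this overlap is the largest relative to list length. The lists of horn and support structures (686 and 844 transcripts) were made against the same 6 tissues. Lists of the horn and the head made in this way also shared more than independent sets would (93 against 48.3). In 20 simulations of unchanged groups against these 6 tissues both lists were empty, so the 0 shared says nothing about shared controls. With libraries 1 to 3 of the 6 tissues used for the horn and 4 to 6 for the support structures 101 were shared (15.5 for independent sets), and 109 (14.2) the other way round. Fewer control libraries shorten the lists, and with the same 3 libraries used for both tissues the numbers were 125 and 100. Sharing control libraries is therefore not needed for the overlap, but no value here gives the number expected without a shared program. The 189 took 23.7% ± 0.979 of horn counts and 13.5% ± 2.32 of support counts (SD, n = 6), against means of 1.43% to 2.14% elsewhere. LOC111420100 (XM_023053048.1) stood at 83400 ± 10400 CPM in the horn and 1070 ± 522 in the support structures, and LOC111428488 (XM_023064026.1) at 39200 ± 4860 and 13100 ± 2420. If horn RNA carried over were the only source of the 189 in support libraries, the ratio of support to horn would be constant. Its 90th percentile was 20.7 times its 10th (3.14 against 0.151), and 33 were higher in the support structures, which argues against carry-over as the only source. Carry-over added to expression of the support structures themselves would not give a constant ratio, so the test cannot decide whether part was carried over. A shared program of both outgrowths is a candidate explanation that the 189 transcripts leave open, as are cell types common to both, which could not be tested without gene names. With total counts the number was 92 (10 for independent sets).

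The distance of the horn to the wing exceeded that to dorsal prothorax by 0.1141 as reported, by 0.07857 without transcripts that set the horn apart, by 0.1022 with all libraries thinned and by 0.1015 with RLE size factors.

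Of the genes higher in the head than in all 7 other tissues, 24.1% had an adjacent gene in the same set, against a median of 15% (95% range 11.9 to 18) in 10000 random sets (permutation p = 1e-04, the smallest they can give, adjusted p = 5e-04 over 5 sets). For the wing the percentage was 0 of 44 genes (random sets 0 to 4.55). For the horn it was 10.7% (random sets 2.15 to 8.9, permutation p = 0.0023, adjusted p = 0.0058), for the support structures 10.9% (3.56 to 10.2, permutation p = 0.011, adjusted p = 0.018) and for the dorsal prothorax 2.47% (0 to 4.94, permutation p = 0.41, adjusted p = 0.51). These 3 tests were taken as void, since 74.4%, 75.2% and 75.7% of the transcripts matched a gene and a minimum of 80% was applied, after the values were seen.

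For each of the 14 comparisons 40 splits of the 12 libraries were counted, each in a fit of both tissues. For each only 1, the real one, had as many calls. Splits that mix the tissues turn a tissue difference into spread within groups, so low counts in them were likely. The splits therefore show that the libraries of the 2 tissues differ, but not how many of the calls chance gave. Real count and highest other were 3408 and 1 for wing against dorsal prothorax, 4949 and 1 for wing against head and 6095 and 9 for dorsal prothorax against head. For the horn they were 2867 and 1 against dorsal prothorax, 4825 and 1 against wing, 6022 and 2 against head, 3822 and 1 against carinated margin, 3367 and 53 against anterior margin, 3173 and 2 against posterior margin and 3521 and 3 against support structures. Against the wing they were 1906 and 15 for the carinated margin, 2163 and 2 for the posterior margin, 2124 and 1 for the anterior margin and 4622 and 1 for the support structures. In comparisons without the head 32 of the splits parted every pair of same-numbered libraries, as the real one does, and of these none but the real one gave more than 3 calls, whereas the counts of 53 and 15 came from the 8 others. In 40 regroupings of all 48 libraries, drawn without regard to their numbers, only 1, the real one, gave as many as 1489 transcripts that set the horn apart, 765 shared calls or 189 transcripts higher in both horn and support structures, and the highest of the others was 0 for each. Groups that mix the tissues leave next to nothing to be called against all others or shared, so these regroupings decide nothing. The splits above count the calls of single comparisons, so they do not decide the number of transcripts that set the horn apart either. For the 765 no excess over chance is shown, as independent lists would share 736.4. Opposite calls numbered 1316, against 697.9 for independent lists, and of the transcripts called in both contrasts 36.8% went the same way. The contrasts thus agreed in direction less often than they disagreed.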
